A study of Homo sapiens with 12 samples.

How the data were processed

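Total RNA depleted of ribosomal RNA, Hi-C cut with DpnII and Capture Hi-C were made from U251 cells with 1 mM TMZ or with DMSO for 72 h, per the labels' protocols. The 12 samples were grouped by assay and treatment from their titles: 2 DMSO and 2 TMZ RNA-seq, 4 DMSO and 2 TMZ Hi-C, and 1 DMSO and 1 TMZ Capture Hi-C. Capture Hi-C was not analysed here.

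The deposited RNA-seq values are raw counts of reads per gene symbol. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 1.18.1 and hg19; the annotation release and strand setting are not given in the sources used here. The files listed 56648 genes. Lines that name no gene stayed out of library sizes and tests: reads with no feature were 4.09 and 3.72% in DMSO replicates 1 and 2 and 4.94 and 4.90% in TMZ, ambiguous reads 11.8, 11.5, 10.5 and 10.7%, reads of low quality 5.52, 5.25, 6.33 and 6.57%, unaligned reads 1.26, 1.19, 2.23 and 2.27%, and reads aligned to several places 17.8, 17.3, 17.8 and 17.9%. Gene counts were 13407788 to 13901371 per library.

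The deposited Hi-C signal is a balanced contact value for each pair of 40 kb bins, 1 matrix per condition with its parts pooled, and every bin with contacts sums to the same total; the submitters' processing notes name HiC-Pro 2.11.1 and Bowtie2 2.3.1. The label of the TMZ matrix carries a code in place of the cell line's name, and whether both matrices came from the same passage or subline is not given in the sources used here. The table of bin positions was not used here. Positions were taken from bin numbers with hg19 chromosome lengths, and checked: at the 24 chromosome ends implied, 0 to 37 contacts crossed, against medians of 1922 (DMSO) and 1412 (TMZ) elsewhere. Contact counts were recovered by finding a factor for each bin, from bins over 2000 bins apart, that makes the values whole; 100% came within 0.05 of a whole number. Intervals from these contacts are Wilson intervals at 95% and cover counting error only, since read duplicates and parts cannot be separated.

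RNA-seq was tested with edgeR 4.0.16 in R 4.3.3: default expression filter (14641 genes), TMM factors, quasi-likelihood fit with group only, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are log2 of TMZ over DMSO, and SEs are the fold change over the square root of F. CPM given for single genes use TMM-scaled library sizes, while summed levels of lists use library totals without TMM factors. The common dispersion was 0.00283, a biological coefficient of variation of 5.32%. Replicates differed by more than sampling noise (chi-square over degrees of freedom 4.08 in DMSO and 2.52 in TMZ), so each counted as 1 sample. For a group at 0 counts a floor of 3 counts over the group was used. The 32 gene lists were p53 targets, checkpoint and recombination repair, alkylation, mismatch and base excision repair, S phase, G2 and mitosis, replication-dependent histones, cholesterol synthesis, unfolded protein and amino acid stress, heat shock, interferon response, NF-kB and senescence secretome, extracellular matrix, exchange factors for Ras-family proteins, Ras-MAPK feedback and immediate early genes, RASGRP3 neighbours, loop and condensin machinery, astrocyte, neuron and oligodendrocyte markers, stem-like genes, hypoxia and glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, lysosome and autophagy, apoptosis, NRF2 targets, lncRNA and small RNA hosts, and blood, epithelial, endothelial, and melanocyte and Schwann markers. The 31 with at least 5 tested members were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated one, and fry. DESeq2 1.42.0 was an alternative.

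Lists, groups, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 CPM and no overlap of groups, RASGRP3 and its listed neighbours, and up to 4 members per list past the threshold with a mean of at least 1 CPM, or up to 2 members where none passed. MGMT, FEZ2, VIT, STRN and HEATR5B and the junctions and chromosome parts given were chosen after their values were seen, and the comparison of coverage and junctions was added after the data were seen. Gene names and gene order came from the GRCh38.p14 gene table, whose coordinates are not used.

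Hi-C was analysed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9. The slope of contact decay was fitted over 20 distance bins. Compartments were the first eigenvector of the correlation of distance-corrected contacts per chromosome at 400 kb, oriented by a between-chromosome eigenvector that is positive on gene-dense chromosomes. Their contrast compared the top and bottom 20% of bins, over at least 2 Mb within chromosomes. Boundaries were the lowest bin within 5 bins and 0.2 (log2) below the maxima within 10 bins on both sides. Contact coverage was compared on the 22 autosomes only, in 1 Mb bins, with segments of at least 10 Mb that differ by 0.15. A junction was a pair of 1 Mb bins on different autosomes with at least 40 contacts and 8 times over the product of their between-chromosome contacts, with a median of at least 5 times over the 9 pairs around it, outside 3 Mb at chromosome ends, merged within 20 Mb. It was in both matrices where the other was at least 5 times over expectation, and in 1 only where the other was under 3 times. Random parts of a matrix drew each contact with probability 0.5.

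The gene test, camera, the recovery of contacts, compartment signs, boundaries, the slope and coverage segments were tested on simulated data; the other steps were not. In 14641 simulated genes, 37 of 64 changed by 1.5-fold (57.8%), 56 of 65 by 2-fold (86.2%) and 66 of 66 by 4-fold were called, with 6 false calls. These leave out changed genes that the expression filter removed from the simulated counts. The simulation changed 200 genes and gave all genes the common dispersion, so its rates need not hold for the data. On a simulated matrix of 5925 bins, all contacts were recovered, 99.4% of compartment signs and 100% of 214 boundaries were found, and a slope of −1 was fitted as −0.999. No annotation of the build of the matrices was used here, so the contacts of RASGRP3 and the relation of compartments to expression were not computed. Alternatives were other scalings, filters, tools and thresholds, a replicate block, each replicate left out, other bin sizes, distances, squares and tolerances, unbalanced contacts, and others chosen after the data were seen.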

Results

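Gene expression and chromosome folding were measured in U251, a human glioblastoma cell line, after 72 h with 1 mM temozolomide (TMZ), an alkylating drug used against glioma, or with its solvent DMSO. RNA-seq of total RNA depleted of ribosomal RNA had 2 DMSO and 2 TMZ samples. Hi-C, which ligates DNA ends that lie close together in the nucleus, had 4 DMSO and 2 TMZ parts, and the deposited values held 1 pooled matrix per condition. Capture Hi-C had 1 sample per condition and was not analysed here. The RNA-seq libraries held 13642673 and 13407788 gene counts in DMSO replicates 1 and 2, and 13564104 and 13901371 in TMZ replicates 1 and 2. The Hi-C matrices held 59314512 contacts in DMSO and 44606900 in TMZ. Nothing in the labels says that the RNA-seq replicates came from separate cultures, so p-values of genes measure the spread between these samples, which may be technical. The p-values of lists by camera with a preset correlation set the genes of a list against the other genes. Their size reflects the number of genes more than the 2 samples per group.

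The first comparison asked which genes changed with TMZ. The largest rises among genes of at least 5 CPM, a read count scaled to library size, were HSH2D, ANGPTL4, BATF2, RSAD2, OASL, LGALS9, ARRDC4, MX2, IGFBP3 and IFITM1. ANGPTL4, a secreted regulator of lipid uptake, went from 0.915 ± 0.293 to 45.4 ± 0.283 CPM (SD, n = 2), a log2 fold change of 5.62 ± 0.20 (SE). RSAD2, an antiviral interferon-induced enzyme, went from 8.74 ± 0.336 to 217 ± 14.2 CPM (SD, n = 2), and MX2, an antiviral GTPase, from 12.2 ± 0.380 to 210 ± 5.54 CPM (SD, n = 2). HSH2D had 2 counts in each DMSO library against 203 and 219 in the TMZ libraries. The largest falls were FOSB, FOS, KRT15, KRT13, NTRK3, AKR1C1, PSD4, GFAP, KCNMA1 and AP000924.1. FOS, a subunit of the AP-1 transcription factor, fell by 5.66 on the log2 scale (SE 0.09), from 276 ± 1.72 to 5.45 ± 0.393 CPM (SD, n = 2), and the related FOSB fell by 5.66 (SE 0.12). KRT15, an intermediate filament keratin, fell by 4.05 (SE 0.11), and GFAP, the intermediate filament protein of astrocytes, by 2.80 (SE 0.05). LGALS9, IFITM1 and AKR1C1 have near-identical relatives, and AP000924.1 may share reads with overlapping genes because the strand setting of the counting is not given in the sources used here, so these 4 values are uncertain.

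Of 14641 genes tested, 3916 were higher and 3922 lower in TMZ by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 1096 were higher and 678 lower by at least 2-fold. DESeq2 called 2556 genes higher, 730 of them by at least 2-fold, and a filter of at least 1 CPM in all 4 samples left 662 genes higher by at least 2-fold. Scaling to library totals, which moves the median gene up by 0.20 (log2), gave 5829 genes higher and 2476 lower, or 70.2% of calls higher against 49.96%, so changes are stated relative to the TMM scale. The libraries also differed outside the genes tested: 2.23 and 2.27% of reads did not align in TMZ against 1.26 and 1.19% in DMSO. Mitochondrially encoded genes, which include tested genes, took 2.98 and 2.92% of gene counts in TMZ against 4.14 and 4.39% in DMSO.

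Genes of the interferon response rose together. All 41 tested members were higher in TMZ, and all 41 also adjusted over the list alone, with a median log2 fold change of 2.28 (adjusted p = 5.28e-150 by camera, and adjusted p = 0.0991 with an estimated correlation). Their summed level, scaled to library totals, was 3227 CPM in DMSO and 17032 CPM in TMZ. OASL, of the oligoadenylate synthetase family, rose by 4.56 ± 0.11 (SE), and XAF1, an interferon-induced promoter of apoptosis, by 5.55 ± 0.41 from 4 and 1 counts in DMSO, with 6.74 without DMSO replicate 1 and 4.90 without DMSO replicate 2. CXCL10, a chemokine, had 0 counts in both DMSO libraries and 41 and 34 in TMZ, and was at least 21.4-fold higher against a floor of 3 counts over the group. The median with the members at 0 placed at their bound was also 2.28. Among NF-kB targets and genes secreted by senescent cells, 18 of 26 tested members were higher and 3 lower, the same counts adjusted over the list alone (median 1.09, adjusted p = 2.31e-09, and adjusted p = 0.125 with an estimated correlation). IL1A, an inflammatory cytokine, rose by 3.44 ± 0.50 (SE) from 2 and 7 counts in DMSO, with 4.58 without DMSO replicate 2 and 2.78 without DMSO replicate 1. BIRC3, an inhibitor of apoptosis induced by NF-kB, rose by 2.52 ± 0.16 (SE), and IGFBP3, a binding protein of insulin-like growth factors, by 3.90 ± 0.12.

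**Figure D1:**
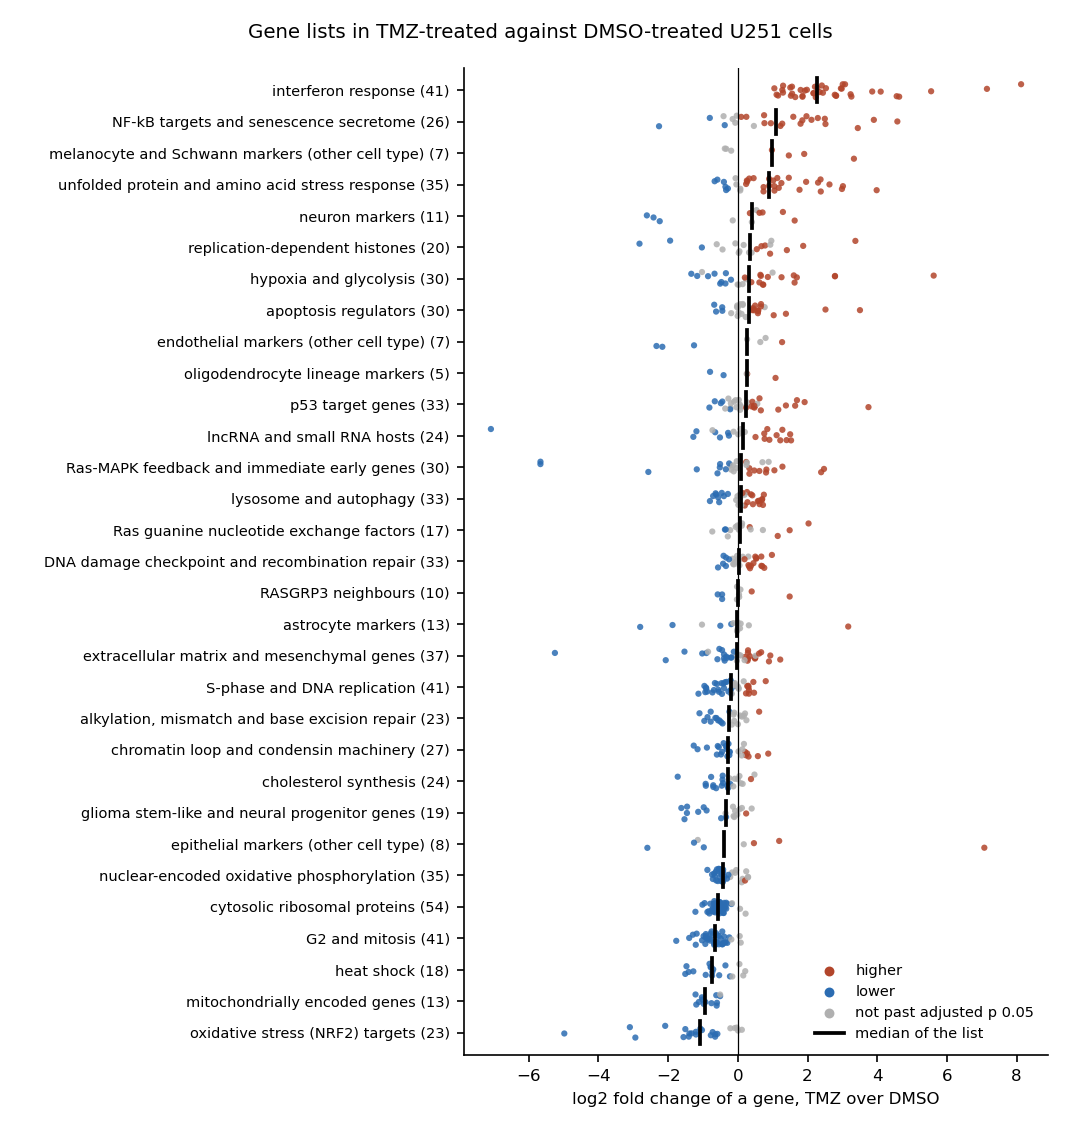
Each point is the log2 fold change of 1 tested gene, TMZ over DMSO (n = 2 per group), by gene list, coloured by edgeR's test, with the number of tested members in brackets and a black bar at the list median. All 41 interferon response genes lie above 0 and none of the cytosolic ribosomal protein genes is called higher; the 4 points of genes with 0 counts in 1 group are fitted values, not bounds.

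Genes of the unfolded protein and amino acid stress response rose. In this list 25 of 35 tested members were higher and 6 lower, the same adjusted over the list alone (median 0.90, adjusted p = 8.75e-19, and adjusted p = 0.106 with an estimated correlation). DDIT3, a stress-induced transcription factor, rose from 8.68 to 70.4 CPM (log2 fold change 3.02 ± 0.14, SE), STC2, a secreted glycoprotein, by 2.99 ± 0.11, and CHAC1, which breaks down glutathione, by 2.63 ± 0.11. Heat shock genes went the other way: 14 of 18 were lower and 0 higher, the same adjusted over the list alone (median −0.73, adjusted p = 1.65e-10, and adjusted p = 0.140 with an estimated correlation). HSPA8 and HSP90AA1, abundant cytosolic chaperones, fell by 1.47 (SE 0.04) and 1.41 (SE 0.04) on the log2 scale, though reads from their pseudogenes cannot be separated. Targets of NRF2, the regulator of the oxidative stress response, were lower in 18 of 23 tested genes and higher in 0, the same adjusted over the list alone (median −1.07, adjusted p = 1.57e-18, and adjusted p = 0.106 with an estimated correlation). TKT, transketolase of the pentose phosphate pathway, fell by 2.08 (SE 0.04), from 2786 to 658 CPM. AKR1C1 fell by 2.94 (SE 0.21) and its near-identical relative AKR1C2 by 3.10 (SE 0.59).

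Targets of p53 were higher in 15 of 33 tested genes and lower in 5, and in 15 and 6 adjusted over the list alone (median 0.24, adjusted p = 4.56e-05, and adjusted p = 0.188 with an estimated correlation). GDF15, a stress-induced cytokine, rose from 85.03 ± 1.67 to 1143 ± 7.87 CPM (SD, n = 2), a log2 fold change of 3.75 ± 0.05 (SE). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.65 ± 0.06, GADD45A by 1.70 ± 0.06 and SESN2 by 1.92 ± 0.11. Apoptosis regulators, with 13 of 30 higher and 4 lower, the same adjusted over the list alone, did not pass the list test (adjusted p = 0.0571), which they passed with library totals (20 higher and 3 lower, adjusted p = 0.0353). BBC3, which encodes the pro-apoptotic protein PUMA, rose by 1.38 ± 0.18 (SE).

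Genes of G2 and mitosis fell. They were lower in 38 of 41 tested members and higher in 0, the same adjusted over the list alone (median −0.65, adjusted p = 8.85e-19, and adjusted p = 0.188 with an estimated correlation). KIF20A, a kinesin of cytokinesis, fell by 1.77 (SE 0.09), the mitotic kinase PLK1 by 1.39 (SE 0.08), and CCNB1, cyclin B1, by 1.29 (SE 0.06) on the log2 scale. S-phase and DNA replication genes were lower in 23 of 41 and higher in 9, the same adjusted over the list alone (median −0.20, adjusted p = 0.0122, and adjusted p = 0.194 with an estimated correlation). With library totals 15 were lower and 12 higher, their median was 0.00, on the other side of 0, and the list call was lost (adjusted p = 0.0726). TYMS, thymidylate synthase, fell by 1.13 (SE 0.09) and MCM6, of the replicative helicase, by 0.96 (SE 0.07). Genes of alkylation, mismatch and base excision repair were lower in 12 of 23 and higher in 1, the same adjusted over the list alone (median −0.24, adjusted p = 0.0265, adjusted p = 0.263 with an estimated correlation, and adjusted p = 0.0502 with library totals, where 10 were lower and 5 higher with a median of −0.04). OGG1, a glycosylase that removes oxidised guanine, fell by 0.96 (SE 0.11) and LIG3, a DNA ligase, by 0.87 (SE 0.10). MGMT, which directly reverses the main toxic lesion of TMZ, had 0 counts in all 4 libraries, under the floor of 3 counts. Checkpoint and recombination repair genes were higher in 14 of 33 and lower in 6, and in 15 and 6 adjusted over the list alone, and did not pass the list test (adjusted p = 0.253), with 17 higher and 2 lower with library totals; BRCA2, of homologous recombination, rose by 0.98 ± 0.11 (SE).

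The list of genes that hold chromosomes in loops or condense them also held lamins. Its members were lower in 17 of 27 tested and higher in 6, and in 17 and 7 adjusted over the list alone (median −0.27, adjusted p = 0.0138, adjusted p = 0.329 with an estimated correlation, and adjusted p = 0.124 with library totals). With library totals 10 were lower and 10 higher, with a median of −0.06, so this fall rests on the scaling. LMNA and LMNB1, which encode lamins of the nuclear envelope, fell by 1.26 (SE 0.05) and 1.15 (SE 0.06) on the log2 scale, and NCAPH, a condensin subunit, by 0.89 (SE 0.08). ESCO1, which acetylates cohesin, rose by 0.87 ± 0.11 (SE).

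Glioma stem-like and neural progenitor genes were lower in 9 of 19 tested members and higher in 1, the same adjusted over the list alone (median −0.34, adjusted p = 1.47e-06, and adjusted p = 0.140 with an estimated correlation). SOX2, a transcription factor of neural progenitors, fell by 1.46 (SE 0.06), FABP7, a fatty acid binding protein of radial glia, by 1.62 (SE 0.14) and ID1 by 1.45 (SE 0.05) on the log2 scale. Astrocyte markers were lower in 4 of 13 and higher in 1, the same adjusted over the list alone (adjusted p = 0.0431, and adjusted p = 0.322 with an estimated correlation), and the call was lost without TMZ replicate 1 (adjusted p = 0.112) and without TMZ replicate 2 (adjusted p = 0.0601). Their median of −0.02 turned to 0.18 with library totals, with 3 lower and 2 higher. GFAP fell from 1123 to 161 CPM, while APOE, a lipid carrier, rose from 1.23 to 11.1 CPM. Extracellular matrix and mesenchymal genes went both ways, with 14 of 37 higher and 16 lower, the same adjusted over the list alone (median −0.03; adjusted p = 0.0840), and with library totals 17 were higher and 10 lower (median 0.18). They passed the list test as lower without DMSO replicate 1 (adjusted p = 0.00577) and without DMSO replicate 2 (adjusted p = 0.00902). VIM, vimentin, fell by 2.07 (SE 0.04) and the hyaluronan receptor CD44 by 1.53 (SE 0.04), while TAGLN, an actin-binding protein, rose by 1.22 ± 0.15 (SE).

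The series title concerns RASGRP3, a guanine nucleotide exchange factor that activates Ras and Rap1, and its regulation by distant chromosome contacts. RASGRP3 rose from 4.85 ± 0.174 to 13.6 ± 0.742 CPM (SD, n = 2), a log2 fold change of 1.49 ± 0.19 (SE, adjusted p = 3.75e-07), with 60 and 62 counts in DMSO and 205 and 195 in TMZ. The adjacent tested genes, LTBP1 and FAM98A, had log2 fold changes of −0.03 ± 0.12 and 0.08 ± 0.08 (SE; adjusted p = 0.879 and 0.434), though with library totals FAM98A was called higher (0.28, adjusted p = 0.00388). Farther out, TTC27 fell by 0.58 (SE 0.13), CRIM1 by 0.45 (SE 0.06) and SPAST by 0.45 (SE 0.13), and BIRC6 rose by 0.40 ± 0.06 (SE). The call of SPAST was lost with library totals (−0.25, adjusted p = 0.106) and without TMZ replicate 1 (−0.35, adjusted p = 0.0694). Of the 12 tested genes flanking RASGRP3, 3 were higher and 4 lower. Among them, chosen after their values were seen, VIT fell by 2.01 (SE 0.31), more than RASGRP3 rose, and FEZ2 by 0.39 (SE 0.08), while HEATR5B rose by 0.45 ± 0.09 (SE) and STRN by 0.34 ± 0.10. The call of STRN was lost without DMSO replicate 1 (adjusted p = 0.0932), without TMZ replicate 2 (adjusted p = 0.0735) and with DESeq2 (adjusted p = 0.0553). The list of RASGRP3 neighbours, which holds RASGRP3 itself, had 2 of 10 tested members higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.942), and 4 higher and 2 lower with library totals. Among exchange factors for Ras-family proteins, 4 of 17 were higher and 2 lower, the same adjusted over the list alone (median 0.05, adjusted p = 0.699), and 8 were higher and 1 lower with library totals. RAPGEF1, which acts on Rap1, fell by 0.37 (SE 0.06). Immediate early genes and feedback regulators of Ras-MAPK signalling went both ways: 11 of 30 were higher and 9 lower, the same adjusted over the list alone (adjusted p = 0.0759), and 15 were higher and 7 lower with library totals. Their median was 0.11, while their mean of −0.17 and the test pointed down, and the list passed without DMSO replicate 1 (adjusted p = 0.0170) and without DMSO replicate 2 (adjusted p = 0.00590). EGR1, a growth factor-induced transcription factor, fell by 2.57 (SE 0.07), and HBEGF, a ligand of the EGF receptor, rose by 2.47 ± 0.12 (SE).

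**Figure D2:**
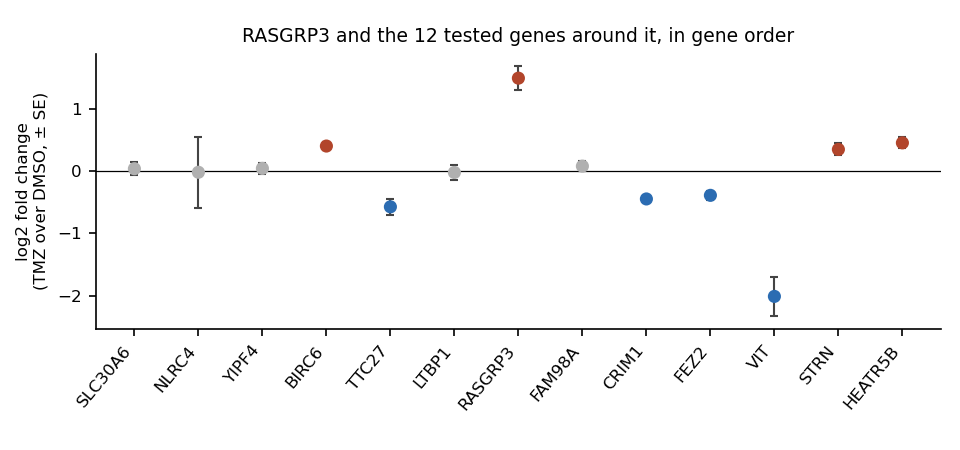
Points are log2 fold changes, TMZ over DMSO, with bars of 1 SE (n = 2 per group), for RASGRP3 and the 6 tested genes on each side in chromosome order; red is higher, blue lower and grey not past edgeR's test. RASGRP3 at 1.49 lies above the other 12, which run from −2.01 to 0.45.

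The second comparison asked how chromosome folding differed with TMZ. Each condition had a single pooled matrix, so no difference below has a replicate check or a test, and intervals cover counting error only. The matrices first differed in how many contacts each chromosome took. Relative to all autosomes, chromosome 18 had a log2 ratio of TMZ to DMSO contacts of −0.58, chromosome 8 of −0.37, chromosome 12 of −0.27 and chromosome 7 of 0.32, while 2 random parts of 1 matrix differed by at most 0.007. The ratio changed in steps within 14 of 22 autosomes, and in 0 between random parts of the DMSO matrix. Chromosome 18 had a median ratio of −0.97 from 20 to 78 Mb and of 0.06 before it, and chromosome 8 of −0.69 from 67 to 132 Mb (hg19 positions throughout, from bin order). Contacts between 2 chromosomes at a single place, as a junction of the 2 gives, were found in 19 places. Both matrices showed 11 of these, such as chromosome 1 at 115 Mb with chromosome 16 at 71 Mb, which was 30.6 times over expectation in DMSO and 30.4 times in TMZ. Of the others, 4 were found in DMSO only, 1 in TMZ only, and 3 lay between the bounds for either. The strongest in DMSO only joined chromosome 10 at 100 Mb to chromosome 16 at 79 Mb, with 783 contacts in DMSO and 8 in TMZ, and both places were steps of the contact ratio. Every folding measure below compares matrices that differ in this way.

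**Figure D3:**
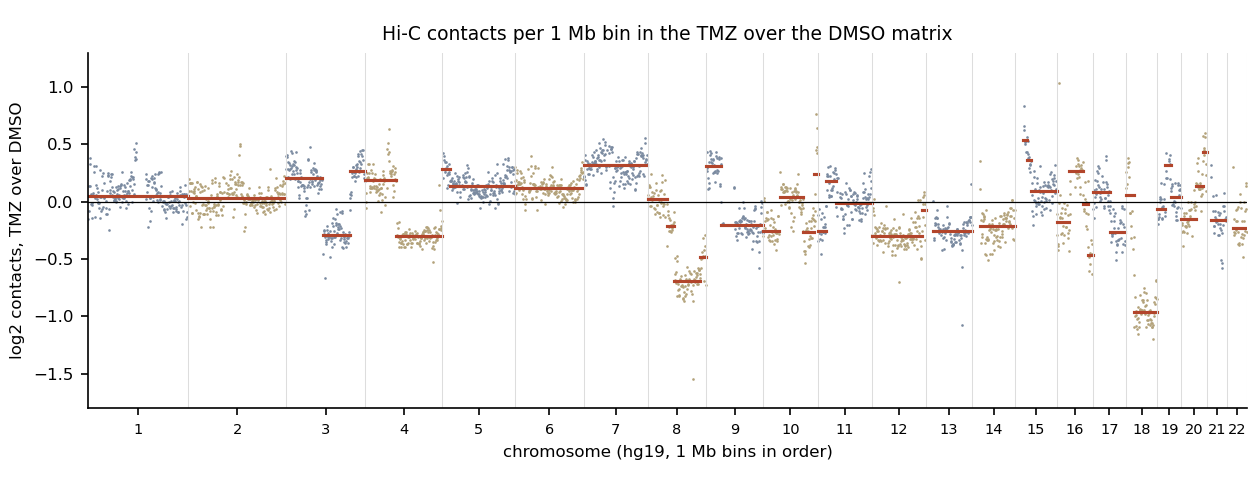
Points are log2 ratios of contacts in the TMZ over the DMSO matrix in 1 Mb bins of the autosomes in order, relative to all autosomes, and red lines are medians of segments of constant ratio (1 matrix per condition). The lowest segment is chromosome 18 from 20 to 78 Mb at −0.97.

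Contacts were less often within a chromosome in TMZ. The within-chromosome share of the balanced signal was 75.2% in DMSO and 66.4% in TMZ, and lower on all 22 autosomes and X. In recovered contacts the shares were 74.4% (95% Wilson interval 74.3 to 74.4) and 65.6% (65.6 to 65.6). Within chromosomes, contacts over 40 kb to 5 Mb took a larger share in TMZ and those over 5 to 50 Mb a smaller one. Contacts over 1 to 2 Mb made up 7.31% of the within-chromosome signal in DMSO and 9.33% in TMZ, those over 10 to 20 Mb 5.86 and 3.91%, and those over 20 to 50 Mb 6.84 and 4.75%. At both ends it went the other way: pairs in the same bin made up 17.9 and 14.6%, and those over 50 Mb 3.32 and 3.52%. The slope of contact frequency on distance from 0.5 to 10 Mb, on log scales, was −1.25 in DMSO and −1.41 in TMZ, a difference of −0.17 that reached −0.29 from 1 to 20 Mb, and it was steeper in TMZ on 23 of 23 chromosomes.

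**Figure D4:**
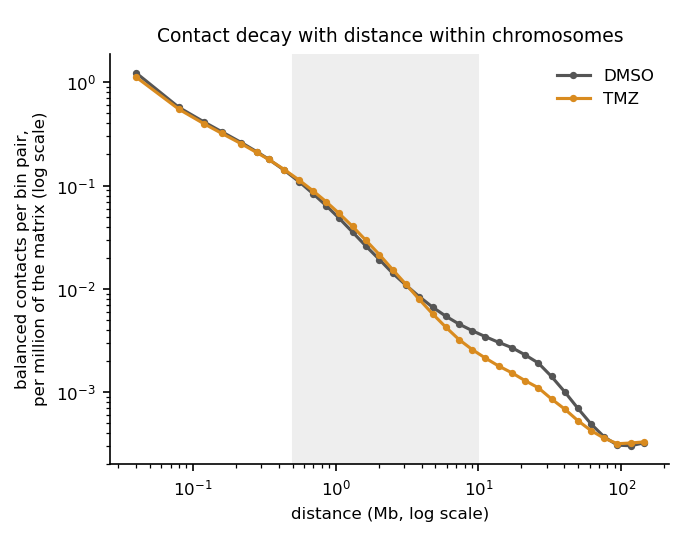
Lines give balanced contacts per pair of 40 kb bins within chromosomes, scaled to the total of the matrix, against distance on log axes, 1 matrix per condition; the grey band marks the 0.5 to 10 Mb of the slope. The slope there was −1.25 in DMSO and −1.41 in TMZ. On this scale DMSO lies above TMZ up to 0.34 Mb and from 3.86 to 76.0 Mb, and TMZ lies above DMSO from 0.44 to 3.10 Mb.

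Compartments, the 2 kinds of chromatin that each contact their own kind, were compared by the sign of the first eigenvector in 400 kb bins, positive in the gene-dense kind. The sign differed in 1305 of 7017 bins (18.6%), against 5.05% between random parts of the DMSO matrix and 6.97% between those of TMZ. Of these bins, 1099 went from positive to negative and 206 the other way, with 0 placed where the eigenvector puts it. Centring each chromosome at its median, which sets the counts near equal by design, gave 509 and 508, so neither split shows a direction. Runs of bins with the largest move from negative to positive lay on chromosome 4 at 65.6 to 68.0 and 59.6 to 65.2 Mb, X at 126.0 to 126.8 Mb, chromosome 13 at 53.6 to 55.6 Mb and chromosome 8 at 116.0 to 116.8 Mb. Those from positive to negative lay on chromosome 18 at 46.8 to 48.8 and 43.2 to 46.0 Mb and on X at 38 to 39.6, 49.2 to 52.0 and 69.2 to 70.4 Mb. With the best of 3 eigenvectors, chosen after the data were seen, the 5 largest moves from positive to negative were all on X, and the largest from negative to positive were on chromosomes 4, 13 and 18, such as chromosome 18 at 36.4 to 43.2 Mb. Several of these runs lay in altered parts of chromosomes. Those on chromosome 18 lay in the part with a contact ratio of −0.97, and that on chromosome 8 in the part at −0.69. The chromosome 4 runs lay between junctions at 56 and 76 Mb found in both matrices. Whether copy number or depth set the eigenvector there was not tested. In TMZ the first eigenvector of chromosomes 13, 18 and X followed the between-chromosome one weakly (rho 0.48, 0.45 and 0.65). These chromosomes had the highest shares of changed bins, 35.4, 37.4 and 33.0%. With the best of 3 eigenvectors the shares were 27.1, 29.4 and 33.0%, and the rho in TMZ was 0.72, 0.63 and 0.65. Part of the changed bins on chromosomes 13 and 18 thus depended on the choice of eigenvector. Contacts of like over unlike compartments were 2.81 within and 2.32 between chromosomes in DMSO, and 2.27 and 1.92 in TMZ.

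Domain boundaries, where contacts across a place are scarce, were mostly found in both matrices. The insulation score, the log2 mean contact across a place in a square of 400 kb, gave 3722 boundaries in DMSO and 3861 in TMZ, of which 3089 lay within 1 bin of one another (81.5% of boundaries). Random parts with 0.5 of a matrix's contacts, thus deeper for DMSO than for TMZ, shared 81.3% (DMSO) and 81.1% (TMZ), and a random part of DMSO shared 75.3% with a random part of TMZ. At the shared boundaries the mean score was −0.61 in DMSO and −0.69 in TMZ, and 63.6% of them scored lower in TMZ. The score also varied more along the genome in TMZ (SD over bins 0.456) than in DMSO (0.405).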

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

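The RNA-seq reads that did not align, which enter no comparison, were above both DMSO libraries in both TMZ libraries: 2.231% and 2.269% in TMZ replicates 1 and 2, against 1.265% and 1.189% in DMSO replicates 1 and 2. The contacts between chromosomes showed 1 junction in the TMZ matrix alone: chromosome 3 at 27 Mb with chromosome 21 at 34 Mb had 95 contacts in TMZ, 19.1 times over expectation, and 8 in DMSO, 1.64 times over expectation.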

How the results depend on the processing

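RASGRP3 kept its direction and its call under all 10 alternatives, with log2 fold changes of 1.42 to 1.69 and a highest adjusted p of 6.05e-06. No called gene or list was called in the opposite direction under an alternative. Of 1419 values of named genes under alternatives, 44 were no longer called and 2 were newly called. Of 278 list tests under alternatives, 27 were no longer called and 15 were newly called. The other fits shared 5717 calls (DESeq2) to 7745 (replicate block) with the 7838 called, with 0 in the opposite direction.

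With DESeq2, 2556 genes were higher and 730 higher by at least 2-fold. With at least 1 CPM in all 4 samples, which removes genes low in either group, 1149 genes changed by at least 2-fold and 662 were higher by that much. With library totals 2476 genes were lower, and 410 by at least 2-fold, from the shift of 0.20 in the median gene. With an estimated correlation 0 lists passed camera, against 18 with the preset one and 25 with fry. Fry tests a list against no change, while camera tests it against the other genes. The setting with an estimated correlation refers its test to 2 residual degrees of freedom, from 2 samples per group. With it 7 lists had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for NF-kB targets (−0.039), NRF2 targets (−0.007) and stem-like genes (−0.022), so correlation did not remove these calls. It was higher for others, such as mitochondrially encoded genes (0.467). Among lists that camera did not call, fry called apoptosis regulators (adjusted p = 0.00231) and exchange factors for Ras-family proteins (adjusted p = 0.0461) as higher. It called extracellular matrix genes (adjusted p = 0.00214) and Ras-MAPK genes (adjusted p = 0.0168) as lower. Neuron, endothelial, and melanocyte and Schwann markers also passed by fry. For the other moved values the cause was not tested.

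Leaving out each replicate in turn, with the lone sample assumed to vary like the other group, gave 6568 to 7228 genes changed, 3232 to 3481 higher, 3336 to 3793 lower, 1531 to 1718 changed by at least 2-fold (934 to 1037 higher, 597 to 688 lower), 17 to 19 lists and log2 fold changes of RASGRP3 of 1.42 to 1.54. The replicate numbers did not pair the RNA-seq samples: the correlation of DMSO 1 minus 2 with TMZ 1 minus 2 across genes was −0.005, and a replicate block called 7890 genes (1742 by at least 2-fold) and 17 lists, with astrocyte markers no longer called (adjusted p = 0.0528).

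The TMZ minus DMSO within-chromosome share of −8.76 points was −8.52 without pairs of a bin with itself. The slope difference of −0.17 was −0.29 over 1 to 20 Mb, which holds the distances that differ most, and −0.18 in unbalanced contacts. Changed compartment signs were 0.797% among bins in the upper part of the eigenvector range in both, a filter that a bin crossing 0 can seldom meet, and 17.9 and 20.6% in bins of 200 kb and 1 Mb. Shared boundaries were 81.5% with 800 kb squares, 56.6% at the same bin and 86.0% within 2 bins. Chosen after seeing the data, the 5 autosomes of 1 segment and a ratio within 0.2 (1, 2, 6, 21 and 22) had 13.8% changed signs. Their unweighted means over chromosomes were a share difference of −8.91 and a slope difference of −0.21, unlike the pooled −8.76 and −0.17. The slope differences ran from −0.15 on chromosome 2 to −0.29 on chromosome 21, so the means are not directly comparable with the pooled values. Also chosen after, changed signs were 16.5% without chromosomes 13, 18 and X and 18.1% with the best of 3 eigenvectors. They were 14.9% with centred eigenvectors and 18.4% with DMSO thinned to the TMZ depth, which left 79.99% of boundaries shared.

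The contacts of RASGRP3 and the relation of compartments to expression, with their alternatives, were not run, since genes were not placed on the bins. Of simulated 1.5-fold changes kept by the filter 57.8% were called. Only 200 genes were changed in that simulation, against 7838 called here, and all genes had the common dispersion. A larger share of changed genes eases the adjusted threshold, so this rate does not carry over to these data. With 1 matrix per condition, no Hi-C difference has a spread between samples.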

Other observations

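Ribosomal protein, mitochondrially encoded and oxidative phosphorylation genes were mostly lower in TMZ. Cytosolic ribosomal proteins were lower in 51 of 54 tested genes and higher in 0, the same adjusted over the list alone (median −0.57, adjusted p = 1.23e-23, and adjusted p = 0.106 with an estimated correlation). RPL3 fell by 1.22 (SE 0.04) and RPLP0 by 1.01 (SE 0.04) on the log2 scale, and processed pseudogenes make single values uncertain. Mitochondrially encoded genes were lower in 12 of 13 and higher in 0, the same adjusted over the list alone (median −0.93, adjusted p = 1.97e-18, and adjusted p = 0.188 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation were lower in 25 of 35 and higher in 1, and in 26 and 1 adjusted over the list alone (median −0.43, adjusted p = 4.56e-05, and adjusted p = 0.188 with an estimated correlation). Cholesterol synthesis genes were lower in 15 of 24 and higher in 1, the same adjusted over the list alone (median −0.29, adjusted p = 0.00377, and adjusted p = 0.188 with an estimated correlation), and with library totals 9 were lower and 4 higher (median −0.09). In hypoxia and glycolysis, 15 of 30 were higher and 9 lower, and 16 and 9 adjusted over the list alone (median 0.31, adjusted p = 0.00377, and adjusted p = 0.243 with an estimated correlation), with the call lost without DMSO replicate 1 (adjusted p = 0.193) and without DMSO replicate 2 (adjusted p = 0.118). CA9, a hypoxia-induced carbonic anhydrase, rose by 2.79 ± 0.12 (SE) and NDRG1 by 2.79 ± 0.08. The list's summed level, scaled to library totals, went the other way, with 16714 CPM in DMSO and 12030 CPM in TMZ. Hosts of small RNAs and other lncRNAs were higher in 11 of 24 and lower in 7, the same adjusted over the list alone (median 0.16, adjusted p = 0.0265, adjusted p = 0.243 with an estimated correlation, and adjusted p = 0.0746 without DMSO replicate 2). SNHG15, which hosts a small nucleolar RNA, rose by 1.53 ± 0.10 (SE). Lysosome and autophagy genes were higher in 14 of 33 and lower in 9 (median 0.10, adjusted p = 0.775), and in 23 and 8 with library totals (median 0.30), and replication-dependent histones, whose mRNAs mostly lack poly(A) tails and whose copies are alike, higher in 7 of 20 and lower in 3 (adjusted p = 0.527), both the same adjusted over the list alone.

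Markers of other cell types mostly did not move as lists against the other genes. By fry, which tests a list against no change, neuron and endothelial markers were called lower (adjusted p = 0.0168 and 0.0197). Melanocyte and Schwann markers were called higher by fry (adjusted p = 0.0160). Oligodendrocyte and epithelial markers were not called by it (adjusted p = 0.0958 and 0.475). Neuron markers were higher in 5 of 11 tested genes and lower in 3 (median 0.40, while the mean of −0.17 and the test pointed down; adjusted p = 0.291), with NEFL, a neurofilament, at 1117 CPM in DMSO and 183 CPM in TMZ. Oligodendrocyte lineage markers were higher in 2 of 5 and lower in 2 (median 0.26, mean 0.08, test down; adjusted p = 0.868), and higher in 3 and lower in 2 adjusted over the list alone. Epithelial markers were higher in 3 of 8 and lower in 3 (median −0.40, mean 0.37, test up; adjusted p = 0.868), and higher in 3 and lower in 4 adjusted over the list alone. Endothelial markers were higher in 1 of 7 and lower in 3 (median 0.27, while the mean of −0.40 and the test pointed down; adjusted p = 0.0654), and passed without TMZ replicate 2 (adjusted p = 0.0259), with at least 1 CPM in all 4 samples (adjusted p = 0.0191) and with library totals (adjusted p = 0.0353). SOX18, an endothelial transcription factor, fell by 2.33 (SE 0.12). Melanocyte and Schwann markers were higher in 4 of 7 and lower in 0 (adjusted p = 0.137), with NGFR, a neurotrophin receptor, at 1.27 CPM in DMSO and 12.9 CPM in TMZ. Of the blood cell markers 3 were tested and 0 passed, too few for a list test, and 0 of the 3 had an unadjusted p under 0.05. Their summed levels, scaled to library totals, were 4.59 CPM in DMSO and 4.84 CPM in TMZ. TMM factors, not applied to these sums, were 0.93 in both DMSO libraries and 1.07 in both TMZ libraries, so the order of the sums depends on the scaling. For the neuron, endothelial, melanocyte and blood lists the counts were the same adjusted over the list alone.

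The tests below that were chosen after the result was seen are those of the shared copy number, unrelated cells, diverged cultures and S phase between segments, of random ligation as the cause of the shorter range, and of the region around RASGRP3.

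The matrices differed in the contacts of whole chromosomes and chromosome parts, by up to 0.5833 (log2) for a chromosome, against 0.0067 between random parts of 1 matrix, which argues against counting noise. Unrelated cells are argued against by the 11 junctions found in both matrices, of which 4 had both ends over 5 Mb from a poorly mapped bin; the rest lay near such bins, where mapping can give the same contacts in both. Also argued against is a changed share of cells in S phase, as the source of the segments, by the 99.98% of the spread between segment means left after removing the slope, fitted within segments, on the between-chromosome compartment eigenvector. The means of that eigenvector differ between segments (SD 0.415, against 0.907 within), and even the best slope between segment means left 99.85%. Within chromosomes the ratio and that eigenvector had a median rho of −0.404, between the bounds set, so part of the finer differences may come from S phase. The 5 junctions found in 1 matrix alone (4 of them over 5 Mb from such bins) go with cultures that had diverged in their chromosomes, as a hypothesis. Over whole chromosomes, RNA fold changes did not follow the contact ratios in proportion (slope of chromosome medians 0.070, 95% interval −0.001 to 0.142). Shared copy numbers with expression in proportion to them would give about 1. Genes were not placed on segments, so copy numbers of chromosome parts were not compared with RNA. With 1 matrix per condition, divergence and treatment stay confounded in every Hi-C difference.

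The lower within-chromosome share was not set by altered chromosomes alone, since it was lower on 22 of 22 autosomes. The compartment contrast between chromosomes had a TMZ minus DMSO difference of −0.3936, against 0.0067 between random parts. More random ligation in the TMZ library would give such a fall and is a candidate explanation. Weaker compartments would also give it, so this contrast cannot tell them apart. An even background of 10.7% of TMZ contacts would give that contrast, and without it the share is 73.7% against 75.2% in DMSO. Without that background the contrast within chromosomes was still 2.36 against 2.81 in DMSO, so the background does not account for that fall. The background also leaves the shorter range as it was, with a slope difference of −0.1714 without it. Fewer mitotic cells in the TMZ culture were predicted to raise the contrast within chromosomes. That contrast was lower (TMZ minus DMSO −0.537, and 2.36 against 2.81 without the background), so they do not explain every folding difference. The larger SD of the insulation score and the fall of mitotic genes go with fewer mitotic cells. Since the contrast may have fallen for a separate reason, whether they set the share and the range stays open. A direct effect of TMZ on folding was not tested apart from these.

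The rise of RASGRP3 was not one of its region: the median log2 fold change of the 12 flanking tested genes was 0.006, with a range of −2.01 to 0.45. Nor was it a general rise at its expression level, since 98% of the 500 tested genes nearest in mean expression had a lower fold change. An effect of TMZ on this gene is an open explanation, as a hypothesis, since only the explanations above were tested. Whether its distant contacts changed was not tested here.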
